A study of Mus musculus with 8 samples.

How the data were processed

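Single-cell 3′ transcriptomes of 8 heart libraries were used, 2 for each of db/m at 8 weeks and db/db at 8, 14 and 20 weeks, with 62234685 to 95220756 UMIs per library. The values used are the deposited UMI counts per gene and barcode, made by the authors with Cell Ranger 6.0.1 against the mouse genome mm10, per the submitters' processing notes and the file headers. The files hold 32285 genes and the barcodes that Cell Ranger kept as cells, with no scaling. The annotation release and the Cell Ranger settings are not given in the sources used here. Per the labels' protocols, hearts were dissociated with trypsin and DNase I at 37 °C, red blood cells were lysed, and suspensions were strained and stained for viability. GENCODE vM21 gave gene positions and matched 32158 of the 32285 gene IDs, and 40 gene symbols that occur more than once were kept apart by ID. The labels' replicates A and B are numbered 1 and 2 here.

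A barcode was kept with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. Scrublet, as built into scanpy, scored doublets per library with an expected rate of 0.06 and 30 components, and cells with a score above 0.25 were removed. That fixed score was chosen after the data were seen, because the automatic threshold called 0 doublets in db/db 14-week 1. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 components and 20 neighbours went into Leiden clustering at resolution 1 with 5 iterations and seed 1. Clusters were named from 21 marker lists fixed before the data, with at least 3 markers detected in at least 10% of the cells, and unnamed cells were left out of the gene tests. A cluster stayed unnamed where haemoglobin transcripts led it, where a second, unrelated class scored 2.5 or more, where its top 10 genes held more markers of another class, or where markers were too few. The 5 most frequent classes with at least 30 cells in each library were tested, and 3 further classes that met the limit are in the closing section.

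UMIs were summed per class and library and tested with edgeR's quasi-likelihood F-test (robust) with TMM scaling, the filterByExpr filter and all 8 libraries in the fit, with 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg within a class and comparison, and an adjusted p under 0.05 counts as changed. Standard errors are the absolute log2 fold change divided by the square root of F. For 36 gene lists fixed before the data, camera with a preset correlation of 0.01 was the test, and an estimated correlation and fry were alternatives. Members are counted as passing over all genes tested in the class or adjusted over the list alone. The lists described were chosen from these results after they were seen. Counts adjusted over a list alone do not allow for that choice, so they describe the list and do not keep the nominal error rate. Cell shares were tested by edgeR on cell numbers per class, for classes with a mean of at least 10 cells per library, with the log of all kept cells as offset. A gene counts as being at the free RNA level where its class has under 10% of the CPM of the class where it is highest, and no correction for free RNA was made.

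Genes are named by a rule fixed before the data. Lepr comes first, in every library. Then come up to 3 rises and 3 falls per class and comparison with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 50 CPM, libraries that do not overlap and at least 10% of the CPM of the highest class. Predicted, mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and Y-linked genes and Xist are left out of that part. Up to 4 members of a list that passed and up to 2 of a list of interest that did not are named too, and sex-linked genes serve as a sample check. Results of some genes that the rule or the tests cover are not reported here.

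Alternatives were DESeq2's size factors in edgeR, DESeq2's own test, no low-count filter, a replicate block, only the 2 groups compared, called doublets kept, at most 10% mitochondrial UMIs, cells thinned to 1000 UMIs, and each library left out in turn. A limit of 5% mitochondrial UMIs and a fit without the 2 db/m libraries were added after the data were seen. In runs with simulated changes, false calls made up 5.63 to 20.6% of calls (median 12.5%), above the nominal 5%. The test recovered a median of 10.3% of 1.5-fold, 40.3% of 2-fold and 84.0% of 4-fold changes over 15 runs. For cell shares, a 4-fold rise of 1 class was recovered in 24% of 50 simulated runs. Random gene lists had an unadjusted p under 0.05 in 0 to 3% of cases by camera. Genes were simulated independently of one another, so these runs do not test camera on lists whose members move together. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, scanpy 1.11.5 and leidenalg 0.10.2.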

Results

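The data are 3′-end single-cell transcriptomes of mouse hearts from the 10x Genomics droplet assay, in which each transcript is counted through a unique molecular identifier (UMI). The db/db mouse carries a recessive mutation of the leptin receptor gene Lepr and becomes obese and diabetic, and the db/m mouse is its lean control. There were 4 groups of 2 libraries each: db/m at 8 weeks and db/db at 8, 14 and 20 weeks of age. A library is named here by its group and replicate number, such as db/m 1 or db/db 20-week 2. The libraries held 62234685 and 62832904 UMIs for db/m and 82325930 and 78750573 for db/db at 8 weeks. They held 78587562 and 95220756 at 14 weeks and 77774351 and 65301452 at 20 weeks. Of 79960 barcodes, 64007 met the limits on UMIs, genes and mitochondrial share, and 62674 remained after called doublets were removed. The comparison of db/db with db/m at 8 weeks asks what differs in the diabetic heart at a matched age. The comparisons of db/db at 14 and at 20 weeks with db/db at 8 weeks ask what differs later, where age and stage move together because no older db/m group was among the samples.

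Lepr (ENSMUSG00000057722, mm10 chromosome 4, 101717404 to 101815352, plus strand) was detected in every library. It stood at 17.0 and 15.4 CPM (counts scaled to the library's total) in whole db/m libraries and 30.2 and 36.4 in db/db at 8 weeks. At 14 weeks it stood at 21.9 and 21.8, and at 20 weeks at 21.9 and 17.9. A 3′ tag does not test the mutation, so these values do not check the genotype labels. Within fibroblasts Lepr did not pass for genotype (log2 fold change ± SE 0.06 ± 0.12, adjusted p = 0.889), at 14 weeks (-0.36 ± 0.12, adjusted p = 0.318) or at 20 weeks (-0.66 ± 0.12, adjusted p = 0.0692). Xist, the transcript of the inactive X chromosome, had 6 to 18 UMIs per library beside 716 or more of the Y-linked Kdm5d, a male pattern in all 8 libraries.

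The db/m libraries stood apart in quality. Their median barcode held 3310 and 3349 UMIs, against 5496 to 10773 in the 6 db/db libraries. Their median mitochondrial share was 24.2% and 18.9% of UMIs, against 3.10 to 6.36%. Haemoglobin transcripts of red blood cells made up 2.46% and 2.18% of UMIs in db/m and 0.225 to 0.629% in db/db. The limits kept 42.6% and 50.4% of db/m barcodes and 90.4 to 98.4% of db/db barcodes. Kept db/m cells still had a median mitochondrial share of 9.97% and 9.39%, against 3.08 to 6.06%. Library quality thus moves with genotype in the 8-week comparison. It also moves with age between 8 and 20 weeks in db/db. The median mitochondrial share of all barcodes was 3.10% and 3.84% at 8 weeks and 5.29% and 6.36% at 20 weeks. In kept endothelial cells it was 4.61% and 5.93% at 8 weeks and 10.8% and 11.7% at 20 weeks.

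**Figure D1:**
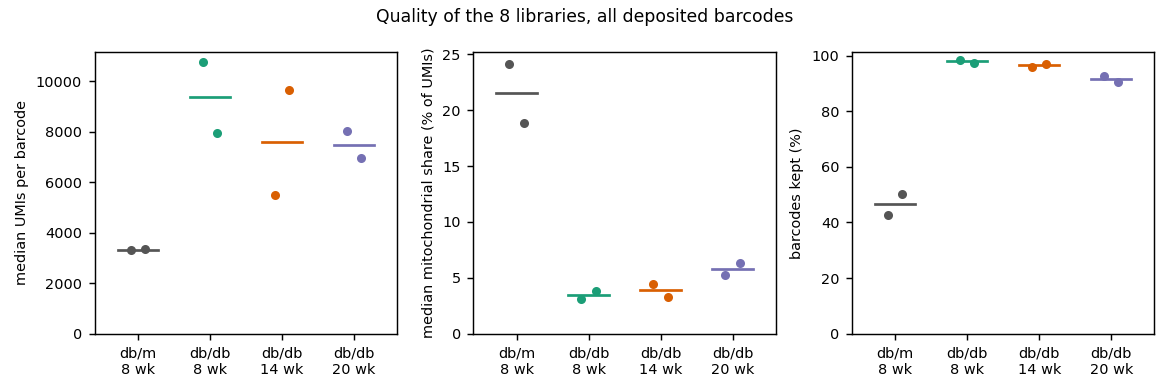
Median UMIs per barcode, median mitochondrial share of UMIs (%) and barcodes kept (%) of the 8 libraries by group, with points for libraries and short lines for group means. The db/m libraries lie at 3310 and 3349 UMIs and at 24.2% and 18.9% mitochondrial UMIs, apart from the 6 db/db libraries.

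Clustering gave 38 groups of cells, of which 12, holding 5052 cells, stayed unnamed. The others were named from marker genes and joined into 16 classes. Each class is "like" its name by markers only (fibroblast-like and so on), and the suffix is dropped from here on. Fibroblasts (31623 cells, marked by Col1a1, Dcn and Pdgfra) and endothelial cells (10373, Pecam1, Cdh5 and Kdr) were the most frequent. Macrophages (4229), endocardial cells (2214, Npr3 and Vwf) and B cells (1960, Cd79a and Ms4a1) followed, and these 5 classes were tested gene by gene. Unnamed cells made up 10.4% ± 1.32 (mean ± SD, n = 2) of db/m cells and 6.25% ± 1.83, 11.8% ± 7.43 and 3.66% ± 0.314 of db/db cells at 8, 14 and 20 weeks. Haemoglobin transcripts led the largest unnamed cluster.

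At 8 weeks endothelial cells made up 11.3% ± 5.14 of db/db and 37.2% ± 12.5 of db/m cells, and fibroblasts 59.5% ± 4.40 and 33.4% ± 10.1. No class changed its share in any of the 3 comparisons by the edgeR test on cell numbers. Endothelial cells (log2 ratio -1.72 ± 0.64, adjusted p = 0.281) and T cells (1.22% ± 0.969 against 0.334% ± 0.131, adjusted p = 0.281) were the 2 classes with an unadjusted p under 0.05 for genotype. Endocardial cells were the 1 such class at 14 against 8 weeks (5.97% ± 0.814 against 1.83% ± 0.315, adjusted p = 0.209). At 20 against 8 weeks there were 0, and no other tool was run on shares. Monocytes averaged 0.135% ± 0.0552 in db/m and 0.776% ± 0.592, 1.88% ± 2.16 and 3.50% ± 2.19 in db/db at 8, 14 and 20 weeks. Neutrophils averaged 0.126% ± 0.178, 0.790% ± 0.188, 1.68% ± 1.51 and 1.90% ± 0.300 in the same order. Dissociation and the quality limits, which removed more db/m barcodes, also set these shares. With at most 10% and 5% mitochondrial UMIs the endothelial ratio for genotype shrank to -0.86 ± 0.72 and -0.48 ± 0.46. With TMM over classes it grew instead, and the fibroblast ratio shrank under each of these settings.

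**Figure D2:**
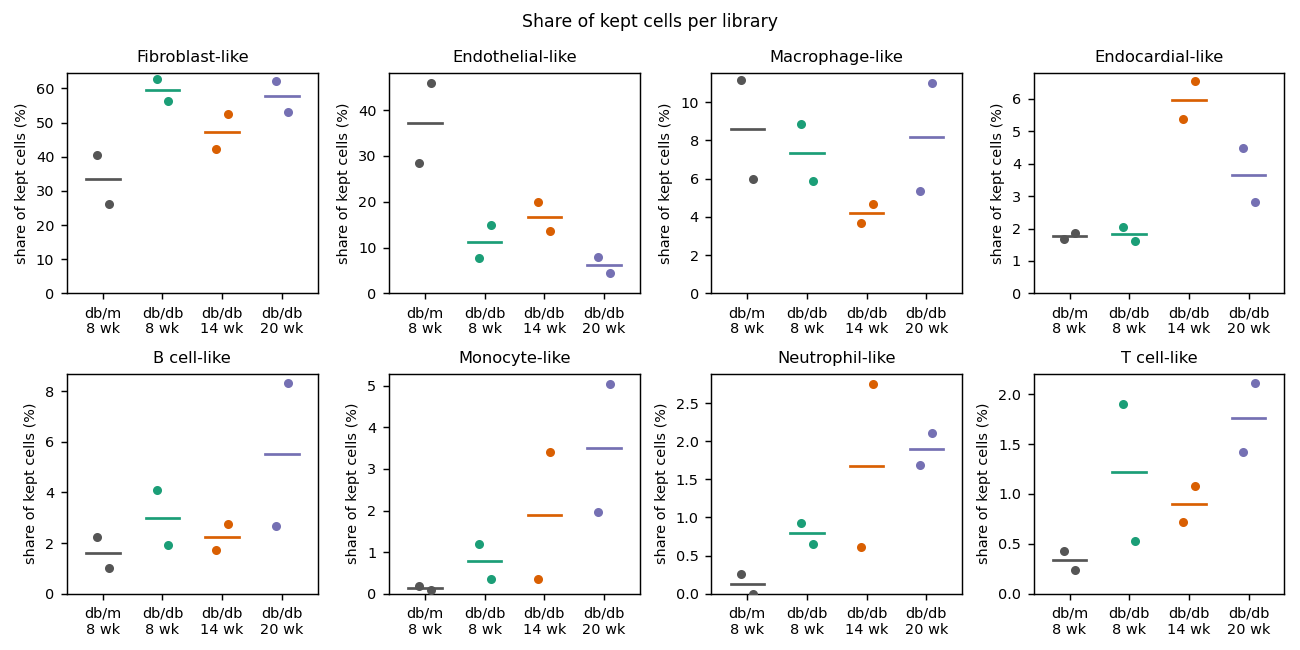
Share of kept cells (%) in 8 cell classes by group, with points for libraries and short lines for group means of 2 libraries. Endothelial cells average 37.2% in db/m and 11.3% in db/db at 8 weeks with wide spread between libraries, and no class passed the test.

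Genes were tested on UMI sums per class and library by edgeR, and CPM values are means ± SD of 2 libraries. The labels do not say that libraries came from separate animals, so the p-values measure only the spread between these libraries. An exact permutation test of 2 against 2 cannot reach p = 0.05. All 3 comparisons share the db/db 8-week libraries, so their results are not independent of one another. Of 107 called values of named genes, 11 kept the call in each alternative processing, among them Swt1 and Tgfbi in fibroblasts and Zfp36 and Hes1 in endothelial cells. Cardiomyocyte transcripts in endothelial cells (Tnni3 and Myl3) and mitochondrially encoded genes in B cells, signs of free RNA and RNA quality, kept it too. Where leaving out 1 library ended the call of a gene named below in these 5 classes, the libraries are named, and the number in parentheses after the gene is its highest adjusted p over all alternatives.

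In fibroblasts of db/db hearts at 8 weeks, heat shock genes and the endoribonuclease homologue Swt1 were lower than in db/m. Swt1 (ENSMUSG00000052748, mm10 chromosome 1, 151367699 to 151428455, minus strand) fell to 74.5 ± 11.5 against 272 ± 5.78 CPM (log2 fold change -1.87 ± 0.12, adjusted p = 0.00239). Its call held in all 17 alternatives. Hspa1a, an inducible HSP70 chaperone (ENSMUSG00000091971, mm10 chromosome 17, 34969190 to 34972156, minus strand), fell to 886 ± 173 against 2065 ± 21.8 CPM (-1.22 ± 0.15, adjusted p = 0.0182). Col4a4, a basement membrane collagen chain, fell as well (-1.31 ± 0.14, adjusted p = 0.0138). Of 14 heat shock genes, 8 fell and 6 did not pass, and all 14 fell when adjusted over the list alone. The median of the list was -0.63 (adjusted p = 2.43e-41 by camera and adjusted p = 0.0726 with an estimated correlation). The HSP40 co-chaperone Dnajb1 (ENSMUSG00000005483, mm10 chromosome 8, 83608193 to 83612653, plus strand) fell to 204 ± 15.9 against 474 ± 28.4 CPM (-1.22 ± 0.11, adjusted p = 0.00692). The chaperone Hsp90aa1 (-0.65 ± 0.07) and the co-chaperones Bag3 (-0.90 ± 0.10) and Hsph1 (-0.92 ± 0.12) fell too.

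In fibroblasts 2 endoplasmic reticulum genes, Dnajb11 and Pdia6, rose at 8 weeks. Of 21 genes of the unfolded protein response, Dnajb11 (0.54 ± 0.08, adjusted p = 0.0269) and the disulfide isomerase Pdia6 (0.86 ± 0.14, adjusted p = 0.0489) rose and 19 did not pass. Adjusted over the list alone, 12 rose. The median of the list was 0.46 (adjusted p = 2.24e-15 by camera and adjusted p = 0.210 with an estimated correlation). The lectin chaperone Calr (0.58 ± 0.10) and the HSP90 homologue Hsp90b1 (0.44 ± 0.09) did not pass. Among 31 collagens and matrix proteins, Col3a1 (-0.63 ± 0.09, adjusted p = 0.0209) and Col14a1 (-0.60 ± 0.09, adjusted p = 0.0249) fell, and 4 fell and 1 rose adjusted over the list alone. That list had a median of -0.11 (adjusted p = 4.98e-05 by camera and adjusted p = 0.293 with an estimated correlation). Tgfbi, a TGF-beta induced matrix protein (ENSMUSG00000035493, mm10 chromosome 13, 56609523 to 56639562, plus strand), fell to 27.0 ± 0.891 against 56.4 ± 0.000123 CPM (-1.07 ± 0.08, adjusted p = 0.00369). The myofibroblast list that holds it did not pass (adjusted p = 0.698).

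The 25 fatty acid oxidation genes did not pass as a list in fibroblasts at 8 weeks (adjusted p = 0.197), and 2 rose and 1 fell adjusted over the list alone. Acaa2, a thiolase, was at 0.58 ± 0.12. Interferon response genes had a median of -0.51 (adjusted p = 0.707 with an estimated correlation), with Ifit1 at -1.09 ± 0.32. Glucocorticoid response genes had a median of 0.50 (adjusted p = 0.707 with an estimated correlation), with Angptl4 at 2.14 ± 0.62. No member of these 2 lists passed, also adjusted over the list alone. Of 13 mitochondrially encoded genes, a measure of RNA quality, 9 fell, and 13 fell adjusted over the list alone. Their median was -1.18 (adjusted p = 0.0726 with an estimated correlation). Of 20 cardiomyocyte transcripts 5 fell, and 15 fell adjusted over the list alone, with a median of -1.76 (adjusted p = 0.0726 with an estimated correlation). The cardiomyocyte troponin Tnni3 was at 5.92 ± 2.51 against 31.6 ± 0.565 CPM in fibroblasts. Glucocorticoid response (0.77 without db/m 1 and 0.31 without db/m 2) was the median above that moved past 1.5 times on leaving out 1 library.

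By edgeR 108 of 15284 fibroblast genes changed at 8 weeks, 19 higher and 89 lower, and 43 of these lie at the level that free RNA of other cells gives. DESeq2 called 333, and edgeR's count was 7 without db/m 1, 14 without db/m 2 and 9 without db/db 8-week 1. It was 31 without db/db 8-week 2, 240 without db/db 20-week 1 and 241 without db/db 20-week 2. Col4a4 (0.161), Bag3 (0.150), Hsph1 (0.187), Dnajb11 (0.286), Col3a1 (0.229) and Col14a1 (0.252) lost their calls without db/m 1, db/m 2, db/db 8-week 1 or db/db 8-week 2. Hspa1a (0.140) and Hsp90aa1 (0.121) lost their calls without db/m 1, db/m 2 or db/db 8-week 1. Dnajb1 (0.0737) lost the call without db/m 1 or db/db 8-week 1. Pdia6 (0.334) lost the call without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2, db/db 20-week 1 or db/db 20-week 2. Tnni3 (0.165) lost the call without db/m 1, db/m 2, db/db 20-week 1 or db/db 20-week 2.

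In endothelial cells of db/db hearts at 8 weeks, the vasoconstrictor endothelin-1 and immediate early genes were higher than in db/m. Edn1 (ENSMUSG00000021367, mm10 chromosome 13, 42301476 to 42307990, plus strand) rose to 97.8 ± 40.6 against 17.5 ± 3.77 CPM (2.44 ± 0.33, adjusted p = 0.0276). Spock2, an extracellular proteoglycan (ENSMUSG00000058297, mm10 chromosome 10, 60106219 to 60135198, plus strand), rose by 2.37 ± 0.37, adjusted p = 0.0376. The histone H4 gene Hist1h4d rose (1.37 ± 0.22, adjusted p = 0.0211), and the long non-coding RNA AU020206 fell (-1.15 ± 0.18, adjusted p = 0.0107). Immediate early genes respond within minutes to stimuli and also to tissue dissociation. Of 22 such genes 6 rose and 16 did not pass, and 14 rose adjusted over the list alone. Their median was 0.66 (adjusted p = 7.71e-15 by camera and adjusted p = 0.163 with an estimated correlation). The mRNA-decay factor Zfp36 (0.97 ± 0.11, adjusted p = 0.00170), the stress factor Atf3 (1.44 ± 0.17, adjusted p = 0.00393), the nuclear receptor Nr4a1 (0.80 ± 0.12) and the AP-1 subunit Junb (0.68 ± 0.11) were among those that rose.

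Glul, the glutamine synthetase, rose (0.93 ± 0.14, adjusted p = 0.00624) among 19 glucocorticoid response genes in endothelial cells, and 7 rose adjusted over the list alone. The list had a median of 1.11 (adjusted p = 0.364 with an estimated correlation). Of 30 collagens and matrix proteins 9 rose and 1 fell, and 17 rose and 5 fell adjusted over the list alone. Their median was 1.12 (adjusted p = 0.538 with an estimated correlation). The matrix protein Fbln2 rose (0.94 ± 0.12, adjusted p = 0.00221) and the laminin chain Lama4 of vessel basement membranes fell (-0.69 ± 0.10, adjusted p = 0.00624). Col1a2 (1.90 ± 0.27) and Col6a3 (2.72 ± 0.47) rose at 0.587% and 0.739% of their level in the class where they are highest, a level that free RNA of fibroblasts can give. The RNA sensor Ifih1 fell (-0.67 ± 0.14, adjusted p = 0.0282) among interferon response genes, and 2 fell adjusted over the list alone. That list had a median of -0.90 (adjusted p = 0.589 with an estimated correlation). MHC class I genes had a median of -0.75 (adjusted p = 0.538 with an estimated correlation) with none past the threshold, for example the peptide transporter Tap1 at -1.16 ± 0.43.

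Mitochondrially encoded transcripts fell for 12 of 13 genes in endothelial cells at 8 weeks, and for 13 adjusted over the list alone. Their median was -1.32 (adjusted p = 0.0981 with an estimated correlation). Cardiomyocyte transcripts fell for 13 of 20, and for 16 adjusted over the list alone, with a median of -1.44 (adjusted p = 0.0981 with an estimated correlation). Myl3, a myosin light chain of heart muscle, was at 34.1 ± 11.7 against 142 ± 0.530 CPM. The make-up of the class differed as well. A cluster marked by Aqp1 and Aplnr held 60.5% of db/m and 32.3% of db/db endothelial cells. A capillary cluster marked by Btnl9 and Cd300lg held 26.7% and 48.6%, and an arterial cluster marked by Sema3g and Hey1 12.7% and 19.1%.

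By edgeR 374 of 11918 endothelial genes changed at 8 weeks, 213 higher and 161 lower, and 151 of them lie at the level of free RNA. The count was 72 without db/m 1, 52 without db/m 2 and 97 without db/db 8-week 1. It was 235 without db/db 8-week 2, 591 without db/db 20-week 1 and 600 without db/db 20-week 2. Edn1 (0.520) lost the call without db/m 1, db/m 2, db/db 14-week 1 or db/db 14-week 2. Spock2 (0.115) lost the call without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2, db/db 14-week 1 or db/db 14-week 2. Hist1h4d (0.157) and Ifih1 (0.824) lost their calls without db/m 1, db/m 2, db/db 8-week 1 or db/db 8-week 2. AU020206 (0.699), Atf3 (0.325) and Col1a2 (0.481) lost their calls without db/m 2. Nr4a1 (0.847) lost the call without db/m 1 or db/db 8-week 1. Junb (0.173) and Col6a3 (0.210) lost their calls without db/m 1, db/m 2 or db/db 8-week 1. Glul (0.655) lost the call without db/m 1 or db/m 2. Lama4 (0.123) lost the call without db/m 1.

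In macrophages of db/db hearts at 8 weeks, Hspb1, Swt1 and Slc5a3 were lower. The small heat shock protein Hspb1 fell to 236 ± 42.0 against 664 ± 34.2 CPM (adjusted p = 0.0338). Swt1 (-1.46 ± 0.21, adjusted p = 0.0338) and the myo-inositol transporter Slc5a3 (-1.44 ± 0.22, adjusted p = 0.0397) fell too. Of 14 heat shock genes Hspb1 fell and 13 did not pass, while 13 fell adjusted over the list alone. The median of that list was -0.88 (adjusted p = 2.99e-25 by camera and adjusted p = 0.143 with an estimated correlation). The median of interferon response genes was -0.65 (adjusted p = 0.567 with an estimated correlation) with none past the threshold. Haemoglobin transcripts of red blood cells were far lower in db/db macrophages, with Hbb-bs at 9.77 ± 0.147 against 1682 ± 113 CPM. Of 6 erythroid transcripts 4 fell, and 6 fell adjusted over the list alone, with a median of -7.28 (adjusted p = 0.00186 with an estimated correlation). Of 13 mitochondrially encoded genes 11 fell, and 13 fell adjusted over the list alone, with a median of -1.71 (adjusted p = 0.0593 with an estimated correlation).

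By edgeR 34 of 11651 macrophage genes changed at 8 weeks, 29 lower and 5 higher, and 12 of them lie at the level of free RNA. The 5 higher genes were named after their values were seen, as each missed the naming rule's limit on mean CPM, overlap of libraries or level against the highest class. They were the apolipoprotein Apoc2 (1.69 ± 0.26, adjusted p = 0.0396), the B-cell cytokine gene Tnfsf13 (1.85 ± 0.29, adjusted p = 0.0435) and Ildr2 (2.06 ± 0.33, adjusted p = 0.0436). The others were the ribonuclease Rnaset2b (2.43 ± 0.31, adjusted p = 0.0168) and the dipeptidase Dpep1 (3.08 ± 0.44, adjusted p = 0.0494). DESeq2 called 161, and edgeR's count was 9 without db/m 1, 14 without db/m 2, 4 without db/db 8-week 1 and 20 without db/db 8-week 2. It was 63 without db/db 14-week 1, 67 without db/db 14-week 2, 113 without db/db 20-week 1 and 112 without db/db 20-week 2. Hspb1 (0.251), Swt1 (0.316), Slc5a3 (0.276), Apoc2 (0.519) and Tnfsf13 (0.751) lost their calls without db/m 1, db/m 2, db/db 8-week 1 or db/db 8-week 2. Hbb-bs (0.556) lost the call without db/db 8-week 1 or db/db 8-week 2. Ildr2 (0.440) and Rnaset2b (0.228) lost their calls without db/m 1, db/m 2 or db/db 8-week 1. Dpep1 (0.480) lost the call without db/m 1, db/m 2, db/db 20-week 1 or db/db 20-week 2.

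In endocardial cells, which line the heart chambers, 2 neighbouring imprinted genes were higher in db/db at 8 weeks. The non-coding RNA H19 (ENSMUSG00000000031, mm10 chromosome 7, 142575529 to 142578143, minus strand) rose to 2379 ± 110.0 against 881 ± 175 CPM (1.44 ± 0.14, adjusted p = 0.00534). The growth factor Igf2 (ENSMUSG00000048583, mm10 chromosome 7, 142650766 to 142666816, minus strand) rose to 1375 ± 282 against 506 ± 38.5 CPM (1.44 ± 0.20, adjusted p = 0.0413). The chaperone genes Dnajb1 (-1.38 ± 0.17, adjusted p = 0.0191) and Hsp90aa1 (-1.02 ± 0.11, adjusted p = 0.00831) fell, as did Swt1 (-1.15 ± 0.15, adjusted p = 0.0292). Of 14 heat shock genes these 2 fell and 12 did not pass, and 8 fell adjusted over the list alone. The median over that list was -0.45 (adjusted p = 1.29e-21 by camera and adjusted p = 0.128 with an estimated correlation). For MHC class I genes the median was -0.76 (adjusted p = 0.264 with an estimated correlation) and interferon response genes -0.89 (adjusted p = 0.633 with an estimated correlation), with no member past the threshold and H2-K1 at -1.08 ± 0.30.

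Mitochondrially encoded genes fell in 4 of 13 cases in endocardial cells at 8 weeks, and in 12 adjusted over the list alone, with a median of -1.07 (adjusted p = 0.128 with an estimated correlation). These 4, H19, Igf2, Dnajb1, Hsp90aa1 and Swt1 are the 9 of 10605 genes called by edgeR. DESeq2 called 40, and edgeR's count was 2 without db/m 1, 0 without db/db 8-week 1, 1 without db/db 8-week 2 and 36 without db/db 14-week 1. It was 34 without db/db 14-week 2, 4 without db/db 20-week 1 and 4 without db/db 20-week 2. H19 (0.0601) lost the call without db/db 8-week 1. Igf2 (0.385) and Hsp90aa1 (0.254) lost their calls without db/m 1, db/m 2, db/db 8-week 1 or db/db 8-week 2. Dnajb1 (0.175) lost the call without db/m 2, db/db 8-week 1 or db/db 8-week 2. Swt1 (0.504) lost the call without db/m 1, db/db 8-week 1, db/db 8-week 2, db/db 20-week 1 or db/db 20-week 2.

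In B cells at 8 weeks, the linker histone genes Hist1h1c and Hist1h1e were higher in db/db. Hist1h1c (ENSMUSG00000036181, mm10 chromosome 13, 23738808 to 23740367, plus strand) rose to 761 ± 181 against 256 ± 52.8 CPM (1.55 ± 0.20, adjusted p = 1.71e-05) and kept the call in all 16 alternatives. Hist1h1e (1.27 ± 0.25, adjusted p = 0.00908) and Bcl2a1d, an anti-apoptotic BCL2 relative (1.66 ± 0.36, adjusted p = 0.0162), rose too. Slc5a3 (-1.84 ± 0.33, adjusted p = 0.00569) and the choline kinase Chka (-1.02 ± 0.25, adjusted p = 0.0466) fell. Of 13 heat shock genes Cryab fell (-3.57 ± 0.85), at 0.131% of its level in the highest class, and 5 fell adjusted over the list alone. That list had a median of -0.62 (adjusted p = 0.732 with an estimated correlation). Mitochondrially encoded transcripts fell for 12 of 13 genes, and for 13 adjusted over the list alone, with a median of -2.00 (adjusted p = 0.0589 with an estimated correlation). Cardiomyocyte transcripts fell for 9 of 17, and for 13 adjusted over the list alone, with a median of -3.41 (adjusted p = 0.0592 with an estimated correlation). Heat shock (-0.37 without db/m 2 and -0.40 without db/db 8-week 1) and cardiomyocyte (-2.23 without db/db 8-week 1) were the medians above that moved past 1.5 times on leaving out 1 library.

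By edgeR 36 of 6739 B-cell genes changed at 8 weeks, 7 higher and 29 lower, and 15 of them lie at the level of free RNA. The count was 89 without db/db 20-week 1 and 92 without db/db 20-week 2. Hist1h1e (0.316) lost the call without db/m 1, db/m 2 or db/db 8-week 1. Bcl2a1d (0.754) lost the call without db/m 1 or db/db 8-week 2. Slc5a3 (0.179) lost the call without db/db 8-week 1. Chka (0.951) lost the call without db/m 1, db/m 2, db/db 8-week 1 or db/db 8-week 2. Cryab (0.439) lost the call without db/m 1 or db/db 8-week 1.

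**Figure D3:**
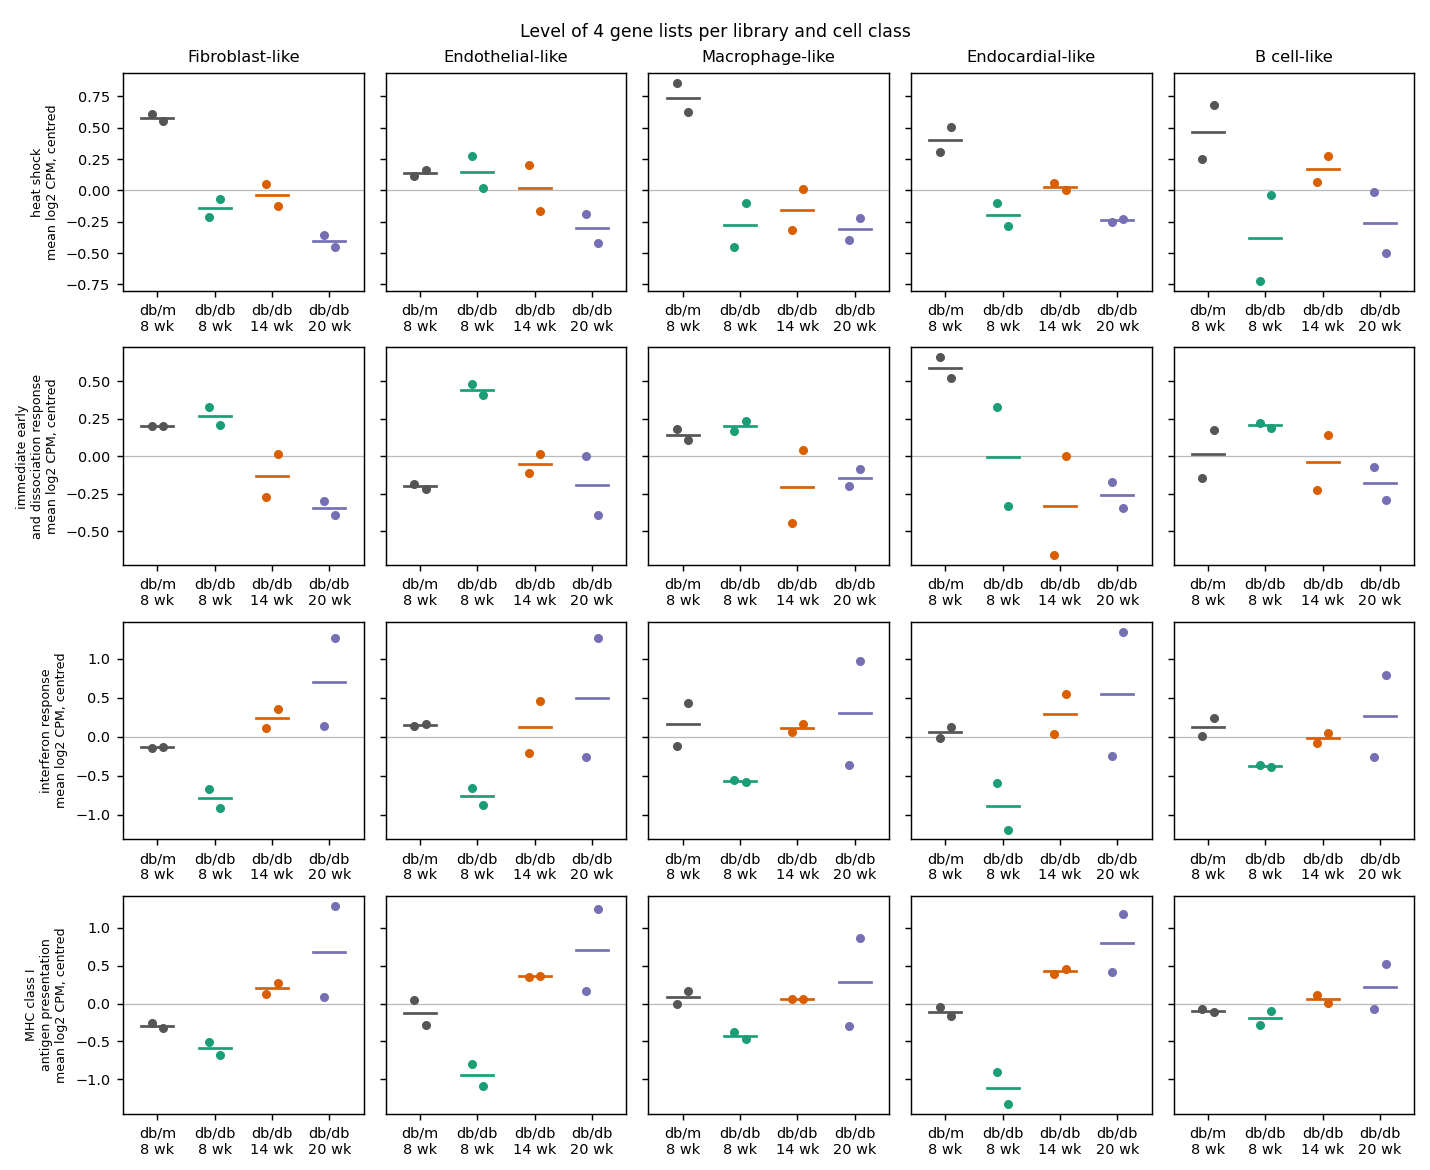
Level of 4 gene lists in 5 cell classes, as the mean log2 CPM of the list minus its mean over the 8 libraries, with points for libraries and short lines for group means. Interferon response genes in fibroblasts lie lowest in the db/db libraries at 8 weeks, at -0.67 and -0.91, and highest in db/db 20-week 2 at 1.27.

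Between 8 and 14 weeks, the immediate early genes Dusp1 and Rhob were among those that fell in db/db fibroblasts. The MAP kinase phosphatase Dusp1 (-0.80 ± 0.08, adjusted p = 0.0255) and the GTPase Rhob (-0.57 ± 0.07, adjusted p = 0.0493) fell. The adhesion receptor Vcam1 (0.67 ± 0.07, adjusted p = 0.0393), Clip4 (0.99 ± 0.10, adjusted p = 0.0255) and Enpp5 (0.92 ± 0.11, adjusted p = 0.0493) rose and the kinase Snrk fell (-0.50 ± 0.06, adjusted p = 0.0493), 4 genes named after their values were seen. Of 22 immediate early genes Dusp1 and Rhob fell and 20 did not pass, and 14 fell adjusted over the list alone. The list had a median of -0.41 (adjusted p = 2.63e-21 by camera and adjusted p = 0.603 with an estimated correlation). Cholesterol synthesis genes had a median of -0.62 (adjusted p = 2.90e-14 by camera and adjusted p = 0.603 with an estimated correlation). None of them passed, 3 fell adjusted over the list alone, and the mevalonate kinase Mvk was at -0.66 ± 0.12.

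Interferon response genes had a median of 0.83 in fibroblasts at 14 against 8 weeks (adjusted p = 0.603 with an estimated correlation). None passed, and 1 rose adjusted over the list alone, with Ifit1 at 1.70 ± 0.30. MHC class I genes had a median of 0.60 (adjusted p = 0.619 with an estimated correlation), with the immunoproteasome subunit Psmb8 at 0.85 ± 0.32. The myofibroblast list did not pass (adjusted p = 0.211), and 2 rose and 3 fell adjusted over the list alone. Collagens and matrix proteins did not pass (adjusted p = 0.351), and 2 rose adjusted over the list alone, with Col14a1 at 0.58 ± 0.09.

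By edgeR 7 of 15284 fibroblast genes changed at 14 against 8 weeks, and 1806 had an unadjusted p under 0.05. DESeq2 called 262, and edgeR's count was 0 without db/m 1, 0 without db/m 2, 0 without db/db 8-week 1 and 0 without db/db 8-week 2. It was 105 without db/db 14-week 1, 4 without db/db 14-week 2, 179 without db/db 20-week 1 and 175 without db/db 20-week 2. Without both db/m libraries it was 0. Dusp1 (0.146), Rhob (0.337), Vcam1 (0.278), Clip4 (0.227), Enpp5 (0.331) and Snrk (0.227) lost their calls without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2 or db/db 14-week 2.

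In endothelial cells at 14 against 8 weeks, the endothelin receptor Ednrb (-0.83 ± 0.10, adjusted p = 0.0320) and the nuclear receptor Nr4a1 (-0.92 ± 0.12, adjusted p = 0.0374) fell. The predicted gene Gm10260 rose (1.76 ± 0.22, adjusted p = 0.0320), and it and Ednrb were named after their values were seen. Of 22 immediate early genes Nr4a1 fell and 21 did not pass, and 15 fell adjusted over the list alone. The median over that list was -0.55 (adjusted p = 6.77e-17 by camera and adjusted p = 0.490 with an estimated correlation). For MHC class I genes the median was 1.34 (adjusted p = 0.490 with an estimated correlation), with the light chain B2m at 1.37 ± 0.36 and the heavy chain H2-K1 at 1.67 ± 0.45. Interferon response genes had a median of 0.79 (adjusted p = 0.538 with an estimated correlation), and no member of these 2 lists passed. By edgeR 3 of 11918 genes changed, and 1212 had an unadjusted p under 0.05. DESeq2 called 39, and edgeR's count was 0 without db/m 1, 0 without db/m 2, 1 without db/db 8-week 1 and 7 without db/db 8-week 2. It was 18 without db/db 14-week 1, 44 without db/db 20-week 1 and 47 without db/db 20-week 2. Nr4a1 (0.343) lost the call without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2 or db/db 14-week 1. Ednrb (0.189) lost the call without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2 or db/db 14-week 2. Gm10260 (0.432) lost the call without db/m 1, db/m 2, db/db 8-week 1 or db/db 8-week 2. Interferon response (0.47 without db/db 14-week 2) was the median above that moved past 1.5 times on leaving out 1 library.

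In macrophages the complement genes Cfb and C3, named after their values were seen, rose at both later ages. Cfb changed by 2.43 ± 0.26 at 14 weeks (adjusted p = 0.0242) and 2.79 ± 0.26 at 20 weeks (adjusted p = 0.0131). C3 changed by 1.98 ± 0.19 (adjusted p = 0.0154) and 1.82 ± 0.19 (adjusted p = 0.0163). Both genes lie at the level that free RNA of another class can give. At 14 weeks immediate early genes had a median of -0.37 (adjusted p = 0.776 with an estimated correlation), and 4 fell adjusted over the list alone, with the shear-stress factor Klf2 at -0.86 ± 0.13. The median of interferon response genes was 0.62 (adjusted p = 0.776 with an estimated correlation), and no member of these lists passed. By edgeR 2 of 11651 genes changed at 14 weeks, and 811 had an unadjusted p under 0.05. DESeq2 called 29, and edgeR's count was 0 without db/m 1, 0 without db/m 2 and 1 without db/db 8-week 1. It was 0 without db/db 14-week 2, 25 without db/db 20-week 1 and 22 without db/db 20-week 2. Cfb (0.787) lost the call without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2, db/db 14-week 1 or db/db 14-week 2. C3 (0.551) lost the call without db/m 1, db/m 2, db/db 8-week 1 or db/db 14-week 2. Immediate early (-0.18 without db/db 14-week 1 and -0.62 without db/db 14-week 2) was the median above that moved past 1.5 times on leaving out 1 library.

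In endocardial cells at 14 against 8 weeks, genes of MHC class I antigen presentation stood higher as a group, without any single gene passing. The 15 members had a median of 1.41 (adjusted p = 1.26e-48 by camera and adjusted p = 0.0842 with an estimated correlation), and 14 rose adjusted over the list alone. H2-K1 was at 1447 ± 365 against 473 ± 22.7 CPM (1.61 ± 0.30) and the proteasome subunit Psmb10 at 1.00 ± 0.17. MHC class II genes had a median of 3.67 (adjusted p = 0.249 with an estimated correlation), and 3 rose adjusted over the list alone. H2-Aa, one of them, was at 49.7 ± 28.2 against 3.01 ± 0.325 CPM, which is 0.436% of its level in the highest class. Interferon response genes had a median of 0.93 (adjusted p = 0.537 with an estimated correlation). By edgeR 0 of 10605 genes changed, 508 had an unadjusted p under 0.05, and DESeq2 called 27. The edgeR count was 4 without db/db 8-week 1, 13 without db/db 14-week 1 and 9 without db/db 14-week 2. It was 5 without db/db 20-week 1 and 5 without db/db 20-week 2.

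In B cells at 14 against 8 weeks, the ubiquitin ligase Neurl3 fell to 91.7 ± 1.16 against 192 ± 0.505 CPM (-1.07 ± 0.19, adjusted p = 0.00572). Smc2, a condensin subunit, fell too (-1.92 ± 0.39, adjusted p = 0.0260). Transcripts of other cells, the pericyte marker Rgs5 (3.31 ± 0.66) and the fibroblast collagen Col1a2 (2.41 ± 0.46), were among 7 that rose. Smc2, Rgs5 and Col1a2 were named after their values were seen. Mitochondrially encoded genes had a median of 0.39 (adjusted p = 0.593 with an estimated correlation), and 7 rose adjusted over the list alone. The median of interferon response genes was 0.58 (adjusted p = 0.720 with an estimated correlation), and 1 rose adjusted over the list alone, with Psmb9 at 0.71 ± 0.22. No member of these 2 lists passed over all genes. By edgeR 9 of 6739 genes changed, and 417 had an unadjusted p under 0.05. DESeq2 called 1, and edgeR's count was 17 without db/m 2, 3 without db/db 8-week 1 and 22 without db/db 8-week 2. It was 36 without db/db 14-week 2, 71 without db/db 20-week 1 and 78 without db/db 20-week 2. Neurl3 (0.845) lost the call without db/db 8-week 1. Smc2 (1.00) lost the call without db/db 8-week 1, db/db 8-week 2, db/db 14-week 1 or db/db 14-week 2. Rgs5 (1.00) lost the call without db/db 8-week 1 or db/db 14-week 2. Col1a2 (1.00) lost the call without db/db 8-week 1 or db/db 14-week 1. Mitochondrially encoded (0.19 without db/db 8-week 1 and 0.60 without db/db 8-week 2) and interferon response (0.07 without db/db 14-week 2) were the medians above that moved past 1.5 times on leaving out 1 library.

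Between 8 and 20 weeks, the complement genes C3 and C1s1 rose and 9 immediate early genes fell in db/db fibroblasts. The central complement component C3 (ENSMUSG00000024164, mm10 chromosome 17, 57203970 to 57228136, minus strand) rose to 1084 ± 207 against 426 ± 1.81 CPM (1.35 ± 0.17, adjusted p = 0.0383). The complement protease C1s1 rose to 193 ± 41.7 against 93.0 ± 1.02 CPM (1.05 ± 0.16, adjusted p = 0.0465). Of 22 immediate early genes 9 fell and 13 did not pass, and 17 fell adjusted over the list alone. The list had a median of -0.63 (adjusted p = 1.29e-35 by camera and adjusted p = 0.28 with an estimated correlation). Atf3 fell to 239.9 ± 0.368 against 505 ± 27.1 CPM (-1.07 ± 0.13, adjusted p = 0.0301). The antiproliferative gene Btg2 (-0.90 ± 0.09), Dusp1 (-0.71 ± 0.08) and Rhob (-0.55 ± 0.07) fell with it.

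Interferon response genes stood higher by median in fibroblasts at 20 against 8 weeks. Of 32 interferon response genes the RNA-binding Ifit1 (2.44 ± 0.30, adjusted p = 0.0455) and the antiviral synthetase Oas1a (2.76 ± 0.46, adjusted p = 0.0465) rose and 30 did not pass, while 29 rose adjusted over the list alone. The median over that list was 1.37 (adjusted p = 2.67e-32 by camera and adjusted p = 0.325 with an estimated correlation). MHC class I genes had a median of 1.15 (adjusted p = 0.325 with an estimated correlation), and 13 rose adjusted over the list alone and none over all genes. A cluster led by Ifit3 and Isg15 held a mean of 0.531% of fibroblasts at 8 weeks and 4.06% at 20 weeks. Counting called doublets, that was 98 cells in db/db 20-week 1 and 269 in db/db 20-week 2, against 31 and 19 at 8 weeks. Tgfbi rose to 50.6 ± 5.60 against 27.0 ± 0.891 CPM (0.91 ± 0.08, adjusted p = 0.0147). Its mean stayed under that of db/m at 8 weeks, so this rise and its fall for genotype rest on the same db/db 8-week libraries. The myofibroblast list did not pass (adjusted p = 0.248), and 3 rose and 3 fell adjusted over the list alone. Col14a1, which had been lower for genotype in the same db/db 8-week libraries, rose (0.52 ± 0.09, adjusted p = 0.0484). Its list of collagens and matrix proteins did not pass (adjusted p = 0.253), and 3 rose and 1 fell adjusted over the list alone. A cluster led by Cilp, Thbs4 and Postn held a mean of 10.7% of fibroblasts at 8 weeks and 22.5% at 20 weeks. Counting called doublets, it held 1588 of 5238 fibroblasts in db/db 20-week 1 and 635 of 4304 in db/db 20-week 2. In db/db 8-week 1 and 2 it held 543 of 4620 and 474 of 4890. Shares of clusters were not tested. Interferon response (0.67 without db/db 20-week 2) and MHC class I (0.46 without db/db 20-week 2) were the medians above that moved past 1.5 times on leaving out 1 library.

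Dnajb1 fell in fibroblasts at 20 weeks (-0.68 ± 0.11, adjusted p = 0.0455) among heat shock genes, and 5 fell adjusted over the list alone. The list had a median of -0.25 (adjusted p = 0.325 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.18 (adjusted p = 0.515 with an estimated correlation), and 10 rose adjusted over the list alone, with Ndufa4 at 0.35 ± 0.07. Mitochondrially encoded genes had a median of 0.67 (adjusted p = 0.325 with an estimated correlation), and 11 rose adjusted over the list alone. By edgeR 82 of 15284 genes changed, 40 higher and 42 lower. The count was 0 without db/m 1, 0 without db/m 2, 0 without db/db 8-week 1 and 1 without db/db 8-week 2. It was 194 without db/db 14-week 1, 192 without db/db 14-week 2, 274 without db/db 20-week 1 and 193 without db/db 20-week 2. Without both db/m libraries it was 0, while 2793 genes had an unadjusted p under 0.05 and DESeq2 called 540 with all libraries. C3 (0.261), C1s1 (0.302), Atf3 (0.182), Btg2 (0.109), Dusp1 (0.0920), Rhob (0.168) and Tgfbi (0.109) lost their calls without db/m 1, db/m 2, db/db 8-week 1 or db/db 8-week 2. Ifit1 (0.275) lost the call without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2, db/db 14-week 1 or db/db 14-week 2. Oas1a (0.201), Col14a1 (0.302) and Dnajb1 (0.190) lost their calls without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2 or db/db 20-week 2. Oxidative phosphorylation (0.11 without db/db 8-week 1) was the median above that moved past 1.5 times on leaving out 1 library.

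In endothelial cells at 20 against 8 weeks, the Notch target Hes1 (ENSMUSG00000022528, mm10 chromosome 16, 30064384 to 30067796, plus strand) fell to 126 ± 4.02 against 331 ± 60.1 CPM (-1.40 ± 0.14, adjusted p = 0.00550). Its call held in all 18 alternatives. The retinol-oxidising dehydrogenase Adh1 (-1.40 ± 0.20, adjusted p = 0.0493) and Socs3, an inhibitor of cytokine and leptin receptor signalling (-1.10 ± 0.16, adjusted p = 0.0481), fell too. Of 22 immediate early genes Junb fell (-0.83 ± 0.11, adjusted p = 0.0310) and 21 did not pass, and 15 fell adjusted over the list alone. The median over that list was -0.55 (adjusted p = 3.55e-18 by camera and adjusted p = 0.306 with an estimated correlation). For MHC class I genes the median was 1.60 (adjusted p = 0.349 with an estimated correlation), and 12 rose adjusted over the list alone, with B2m at 1.93 ± 0.37. MHC class II genes had a median of 3.29 (adjusted p = 0.349 with an estimated correlation), and 6 rose adjusted over the list alone, with H2-Ab1 at 0.169% of its level in the highest class. No MHC gene passed over all genes. MHC class I (0.91 without db/db 20-week 2) and MHC class II (2.16 without db/db 20-week 2) were the medians above that moved past 1.5 times on leaving out 1 library.

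Collagens and matrix proteins had a median of -0.63 in endothelial cells at 20 against 8 weeks (adjusted p = 0.439 with an estimated correlation), and 13 fell adjusted over the list alone. The basement membrane collagen Col4a2 was at -0.50 ± 0.11. Fatty acid oxidation genes had a median of 0.25 (adjusted p = 0.378 with an estimated correlation), and 5 rose adjusted over the list alone, with Cpt1a at 0.60 ± 0.15. Mitochondrially encoded genes rose in 4 of 13 cases, and in 13 adjusted over the list alone, with a median of 0.99 (adjusted p = 0.306 with an estimated correlation). Plaat3 rose (0.91 ± 0.14), and Atoh8 (-1.21 ± 0.17), Vgll4 (-0.68 ± 0.10), N4bp3 (-0.94 ± 0.10) and the tubulin Tubb2a (-0.84 ± 0.13) fell, 5 genes named after their values were seen. By edgeR 13 of 11918 genes changed. DESeq2 called 149, and edgeR's count was 5 without db/m 1, 5 without db/m 2, 5 without db/db 8-week 1 and 32 without db/db 8-week 2. It was 60 without db/db 14-week 1, 64 without db/db 14-week 2, 105 without db/db 20-week 1 and 31 without db/db 20-week 2. Without both db/m libraries it was 5. Adh1 (0.137), Socs3 (0.553) and Tubb2a (0.133) lost their calls without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2, db/db 20-week 1 or db/db 20-week 2. Junb (0.851) lost the call without db/m 1, db/m 2 or db/db 8-week 1. Plaat3 (0.351) and Vgll4 (0.826) lost their calls without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2 or db/db 20-week 2. Atoh8 (0.463) lost the call without db/m 1, db/m 2, db/db 8-week 1, db/db 8-week 2 or db/db 20-week 1. Collagen and matrix (-0.35 without db/db 8-week 1 and -0.996 without db/db 8-week 2) and fatty acid oxidation (0.11 without db/db 8-week 2 and 0.10 without db/db 20-week 1) were the medians above that moved past 1.5 times on leaving out 1 library.

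In macrophages at 20 against 8 weeks, markers of monocyte-derived cells and interferon response genes stood higher by median without single genes passing. Monocyte-derived macrophage markers had a median of 0.68 (adjusted p = 0.231 with an estimated correlation), and 2 rose adjusted over the list alone, with the chemokine receptor Ccr2 at 131 ± 0.771 against 66.2 ± 9.11 CPM (0.99 ± 0.32). Interferon response genes had a median of 1.08 (adjusted p = 0.692 with an estimated correlation), and 5 rose adjusted over the list alone, with the restriction factor Ifitm3 at 0.64 ± 0.16. MHC class I genes had a median of 0.83 (adjusted p = 0.692 with an estimated correlation), with B2m at 0.97 ± 0.25. Oxidative phosphorylation genes had a median of 0.30 (adjusted p = 0.451 with an estimated correlation), and 10 rose adjusted over the list alone. For mitochondrially encoded genes it was 1.01 (adjusted p = 0.231 with an estimated correlation), with 12 higher adjusted over the list alone. By edgeR 2 of 11651 genes changed, Cfb and C3, and 1094 had an unadjusted p under 0.05. DESeq2 called 55, and edgeR's count was 0 without db/m 1, 1 without db/db 8-week 1, 116 without db/db 20-week 1 and 73 without db/db 20-week 2. Without both db/m libraries it was 0. Cfb (0.108) lost the call without db/m 1, db/db 8-week 1 or db/db 8-week 2. C3 (0.198) lost the call without db/m 1, db/m 2 or db/db 8-week 1. Monocyte-derived macrophage (0.21 without db/db 20-week 1), interferon response (0.21 without db/db 20-week 2) and MHC class I (1.34 without db/db 20-week 1 and 0.11 without db/db 20-week 2) were the medians above that moved past 1.5 times on leaving out 1 library.

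In endocardial cells at 20 against 8 weeks, MHC class I genes stood higher, with a median of 1.73 over 15 genes (adjusted p = 3.53e-64 by camera and adjusted p = 0.122 with an estimated correlation). All 15 rose adjusted over the list alone and none over all genes, with H2-K1 at 2162 ± 873 against 473 ± 22.7 CPM (2.19 ± 0.31). The median of interferon response genes was 1.38 (adjusted p = 0.351 with an estimated correlation), and 8 rose adjusted over the list alone. MHC class II genes had a median of 4.30 (adjusted p = 0.236 with an estimated correlation), and 4 rose adjusted over the list alone, with H2-Aa at 68.2 ± 26.1 against 3.01 ± 0.325 CPM. By edgeR 0 of 10605 genes changed, 708 had an unadjusted p under 0.05, and DESeq2 called 19. The edgeR count was 1 without db/db 8-week 1, 1 without db/db 8-week 2 and 7 without db/db 14-week 1. It was 7 without db/db 14-week 2, 15 without db/db 20-week 1 and 4 without db/db 20-week 2. Interferon response (0.54 without db/db 20-week 2) was the median above that moved past 1.5 times on leaving out 1 library.

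In B cells at 20 against 8 weeks, the immunoproteasome subunit Psmb9 (ENSMUSG00000096727, mm10 chromosome 17, 34181987 to 34187764, minus strand) rose to 141 ± 45.5 against 67.1 ± 3.70 CPM (1.13 ± 0.20, adjusted p = 0.00180). The histone gene Hist1h4d fell to 75.8 ± 2.28 against 157 ± 20.1 CPM (-1.05 ± 0.18, adjusted p = 0.00119). Psmb9 was the 1 called member of the interferon response list, which had a median of 0.84 (adjusted p = 0.360 with an estimated correlation) and 5 higher adjusted over the list alone. It was also the 1 called member of the MHC class I list, with a median of 0.51 (adjusted p = 0.360 with an estimated correlation) and 9 higher adjusted over the list alone. Mitochondrially encoded genes rose in 10 of 13 cases, and in 13 adjusted over the list alone, with a median of 1.33 (adjusted p = 0.181 with an estimated correlation). Among them mt-Co1 and mt-Nd5 kept the call in all 17 alternatives. By edgeR 25 of 6739 genes changed, 19 higher and 6 lower. DESeq2 called 13, and edgeR's count was 47 without db/m 2, 40 without db/db 14-week 1, 42 without db/db 14-week 2 and 84 without db/db 20-week 1. Psmb9 (0.419) lost the call without db/db 8-week 1 or db/db 20-week 2. Hist1h4d (0.149) lost the call without db/db 8-week 1. Interferon response (1.31 without db/db 20-week 1 and 0.15 without db/db 20-week 2) and MHC class I (0.15 without db/db 20-week 2) were the medians above that moved past 1.5 times on leaving out 1 library.

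**Figure D4:**
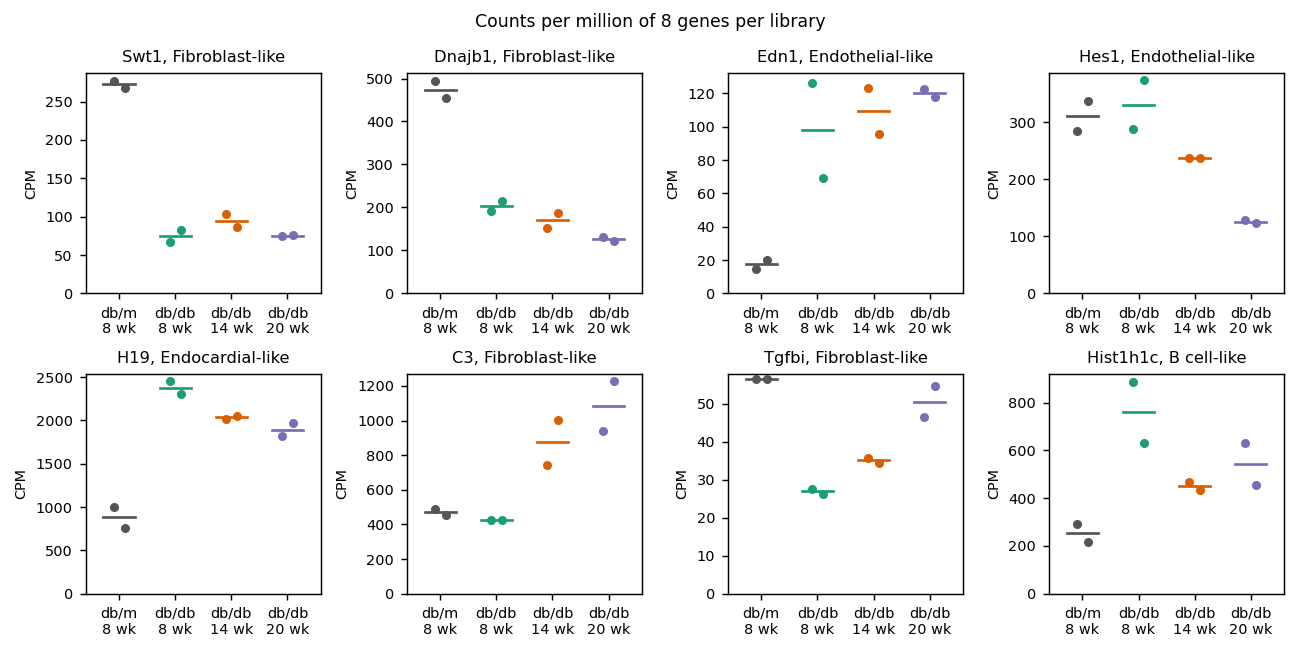
CPM of 8 named genes in the cell class given in each title, by group, with points for libraries and short lines for group means of 2 libraries. Swt1 in fibroblasts averages 272 CPM in db/m and 74.5 in db/db at 8 weeks, and Hes1 in endothelial cells averages 331 and 126 in db/db at 8 and 20 weeks.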

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

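Of the tests in this part, the one-library, heat shock difference, cluster 13 and Edn1 mitochondrial tests were written after their results were seen, and the others after the patterns but before their own results. An edgeR test of the difference between endothelial cells and fibroblasts of the same libraries was read for genes named as largest rises or falls. Of these, 5 changed differently between the classes. For genotype, Swt1 differed by 1.55 ± 0.13, adjusted p = 4.18e-05 (log2, endothelial minus fibroblast), Hspa1a by 1.98 ± 0.22, adjusted p = 0.0111 and Hist1h4d by 0.77 ± 0.12, adjusted p = 0.00376. Their changes in fibroblasts and endothelial cells were -1.87 and -0.30, -1.22 and 0.76, and 0.59 and 1.37. At 20 against 8 weeks, Adh1 differed by -2.22 ± 0.25, adjusted p = 0.0113 and Hes1 by -0.74 ± 0.11, adjusted p = 0.0149. Adh1 changed by 0.76 and -1.40 in the 2 classes and Hes1 by -0.67 and -1.40. Of 14895 genes, 387, 22 and 34 differed in the genotype, 14-week and 20-week comparisons.

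Heat shock genes were lower in db/db than db/m fibroblasts, and handling stress in the low-quality db/m libraries is the rival of a genotype effect. With at most 5% mitochondrial UMIs the median was -0.89 against -0.63 in all kept cells, which argues against cells of high mitochondrial share as the only source. Stress in the db/m cells that remain is not tested by it. A first test of handling asked in how many of 8 classes both db/db libraries lay below both db/m libraries, and the answer, 7 with endothelial cells as the exception, with 0 classes above, favoured handling. It was replaced, after the Hspa1a difference was seen, by a count of members whose change differs between endothelial cells and fibroblasts, with limits of 3 and 7 set at that point. Of 14 members 5 differed (Hspe1, Bag3, Dnajb1, Hspa1b and Hspa1a), a count between the limits. For all 5 the change was higher in endothelial cells, so these 5 did not change alike in the 2 classes. The count decides nothing about handling, because the limits followed the results. The test recovered 18.9% of simulated 2-fold differences for genotype. Those were in genes drawn at random, with the same spread set for every gene, so the rate for heat shock genes is not known. Handling of the db/m libraries, alike or not over cell classes, and a genotype effect cannot be told apart, because both db/m libraries used here are of low quality.

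Interferon response and MHC class I genes stood higher at 20 than at 8 weeks, which may reflect 1 animal or library, since db/db 20-week 2 was highest. Without that library 0 of 5 classes kept over 0.5 of the interferon median (49.0%, 40.2%, 19.3%, 39.3% and 17.7% in fibroblasts, endothelial cells, macrophages, endocardial cells and B cells) and 2 of 5 kept it for MHC class I (40.2%, 56.8%, 12.6%, 71.8% and 30.1%), which first counted as fitting a 1-library source for interferon, but leaving out a library picked as the highest must lower the median. In all 5 classes, db/db 20-week 1 lay above both 8-week libraries for both lists. Interferon medians at 14 weeks, 0.58 in B cells to 0.93 in endocardial cells, do not rest on db/db 20-week 2. In B cells and endothelial cells, however, these medians shrank without db/db 14-week 2. Both ages are also compared with the same db/db 8-week libraries, which lay lowest for interferon response genes in fibroblasts. Low 8-week libraries would raise the medians at both ages, and this was not tested. With 1 library left at 20 weeks, 1 library, low 8-week libraries and age or stage, itself untested, cannot be told apart. Free RNA of macrophages accounts for a median of 0.866% of the rise of MHC class I members in fibroblasts and at most 1.63% (Nlrc5). Free RNA of B cells accounts for less, which excludes these 2 sources there, while free RNA of other classes was not tested. For MHC class II in endothelial cells the median is 34.6%, with 10.6% (H2-DMb1) to 89.3% (Ctss) over members, so free RNA and expression cannot be told apart, because the median lies between the limits of 10% and 50%.

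Edn1 was higher in db/db endothelial cells, and a shift between endothelial clusters could give that. In the test written first the change was 0.69 ± 1.14 in cluster 4 and 0.96 ± 0.54 in cluster 6 (29.0 against 14.4 CPM). Both are under 0.5 of the 2.44 over all endothelial cells and cluster 13 is not, so that test was undecided. With such spreads a change within clusters 4 and 6 is not settled. Clusters 4, 6 and 13 held 60.5%, 26.7% and 12.7% of db/m and 32.3%, 48.6% and 19.1% of db/db endothelial cells. No share grew by as large a factor as Edn1, which argues against a shift alone as the source over all endothelial cells. In the arterial cluster 13 alone, a test added after the values were seen, Edn1 rose by 2.03 ± 0.18 (adjusted p = 6.06e-06 by edgeR). A shift between the 3 clusters cannot give a rise inside 1 of them, while a shift of cells within cluster 13 was not tested. With at most 5% mitochondrial UMIs the change of Edn1 over all endothelial cells was 2.98 ± 1.00 against 2.44 ± 0.33 before. That argues against cells of high mitochondrial share, though the call ended (adjusted p = 0.520 by edgeR) with 23 and 90 db/m cells left. A genotype effect and handling of the db/m libraries both stay open for Edn1, and no test here sets them apart.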

How the results depend on the processing

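The limits of 5% mitochondrial UMIs and the fits without the 2 db/m libraries were chosen after the data were seen. Of 107 called values of named genes, 11 kept the call in all alternatives: Swt1 and Tgfbi in fibroblasts, Zfp36, Tnni3 and Myl3 in endothelial cells and Hist1h1c, mt-Nd4l and mt-Nd5 in B cells for genotype, and Hes1 in endothelial cells and mt-Co1 and mt-Nd5 in B cells at 20 weeks. Over all alternatives, 1368 of 1824 values of called genes kept direction and call, 454 lost the call and 2 reversed. Of 3054 values of named genes without a call, 444 gained one. The 2 reversed values, and Zfp36 (at 0.33), which had no call, reversed in endothelial cells at 20 weeks with at most 5% mitochondrial UMIs, without passing there, with 26 and 13 endothelial cells left at 20 weeks: Junb at 0.11 and mt-Nd4l at -0.0528. Recovery of 2-fold changes was 22.2 to 67.8% over the simulated runs, which had the depth and the 2 libraries per group of these data. The cause of the moved counts and reversed values was not tested.

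Counts are given in the order genotype, 14 and 20 weeks. As reported, genes changed were 108, 7 and 82 in fibroblasts, 374, 3 and 13 in endothelial cells, 34, 2 and 2 in macrophages, 9, 0 and 0 in endocardial cells, 36, 9 and 25 in B cells, and gene lists 15, 8 and 19 in fibroblasts, 17, 14 and 12 in endothelial cells, 19, 11 and 12 in macrophages, 10, 9 and 13 in endocardial cells, 6, 12 and 11 in B cells. Counts of genes with DESeq2's test were 333, 262 and 540 in fibroblasts, 382, 39 and 149 in endothelial cells, 161, 29 and 55 in macrophages, 40, 27 and 19 in endocardial cells, 30, 1 and 13 in B cells. No low-count filter gave 414, 264 and 650 in fibroblasts, 1162, 378 and 513 in endothelial cells, 682, 326 and 470 in macrophages, 147, 156 and 145 in endocardial cells, 84, 54 and 76 in B cells. Only the 2 groups compared, with fewer libraries in the fit, gave 599, 37 and 0 in fibroblasts, 1197, 30 and 25 in endothelial cells, 320, 14 and 0 in macrophages, 64, 0 and 4 in endocardial cells, 53, 74 and 58 in B cells. Called doublets kept gave 80, 4 and 82 in fibroblasts, 275, 7 and 30 in endothelial cells, 42, 1 and 1 in macrophages, 28, 4 and 20 in B cells. At most 10% mitochondrial UMIs gave 227, 16 and 24 in endothelial cells, 22, 8 and 21 in B cells, and at most 5% gave 41, 14 and 155 in endothelial cells, 3, 1 and 5 in macrophages, 1, 0 and 3 in endocardial cells. Cells thinned to 1000 UMIs gave 75, 26 and 110 in fibroblasts, 163, 8 and 19 in endothelial cells, 41, 3 and 16 in macrophages, 11, 0 and 9 in endocardial cells, 5, 0 and 7 in B cells. Thinning left out 0 to 13.3% of cells. Without the 2 db/m libraries the 14-week and 20-week counts were 0 and 0 in fibroblasts, 0 and 5 in endothelial cells, 0 and 0 in macrophages. DESeq2's size factors in edgeR moved no count past 1.5 times, and most in endocardial cells for genotype, to 12. A class is left out above where none of its 3 counts moved past 1.5 times.

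Counts of lists with an estimated correlation were 0, 0 and 0 in fibroblasts, 0, 0 and 0 in endothelial cells, 1, 0 and 0 in macrophages, 0, 0 and 0 in endocardial cells, 0, 0 and 0 in B cells. By fry they were 6, 1 and 1 in fibroblasts, 10, 0 and 0 in endothelial cells, 2, 1 and 1 in macrophages, 0, 0 and 0 in endocardial cells, 1, 0 and 0 in B cells. Thinning gave 10, 9 and 7 in endothelial cells, 15, 6 and 11 in macrophages, 6, 6 and 6 in endocardial cells, 6, 6 and 8 in B cells. At most 5% mitochondrial UMIs gave 11, 10 and 12 in macrophages, 10, 9 and 8 in endocardial cells. No share changed as reported. At most 10% mitochondrial UMIs gave 1 for genotype (neutrophils), which is not used because 2 and 0 neutrophils are left in db/m. At most 5% gave 1 at 14 weeks (endocardial cells, 1.80, adjusted p = 0.0359) and 2 at 20 weeks (endothelial cells, -3.48, adjusted p = 0.00344, and pericytes, -3.45, adjusted p = 0.00344), with 26 and 13 endothelial cells and 7 and 5 pericytes left at 20 weeks. For genotype, the share ratio of endothelial cells moved from -1.72 ± 0.64 to -0.86 ± 0.72 at 10%, -0.48 ± 0.46 at 5% and -2.63 ± 0.72 with TMM over classes, and that of fibroblasts from 0.83 ± 0.53 to 0.23 ± 0.59, 0.12 ± 0.32 and 0.03 ± 0.43. That of T cells moved from 1.86 ± 0.75 to 1.04 ± 0.68 with TMM. TMM over classes moved no share count. In B cells the limit of 5% was not run, because a db/m library keeps 0 B cells.

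With the replicate number as a block (replicate block), counts of genes were 72, 0 and 23 in fibroblasts, 347, 2 and 8 in endothelial cells, 38, 2 and 5 in macrophages, 3, 0 and 3 in endocardial cells, 36, 14 and 22 in B cells. Of these 15, the block moved 7 past 1.5 times, and it moved no count of lists or shares that far. Deviations of libraries with the same number correlated at -0.30 to 0.24 over classes and pairs of groups, so the numbers are not read as pairing the libraries.

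Leaving out 1 library gives ranges, in which the lone library left in a group is assumed to vary like the other groups. Genes changed ranged over 7 to 241, 0 to 179, 0 to 274 in fibroblasts, 52 to 600, 0 to 47, 5 to 105 in endothelial cells, 4 to 113, 0 to 25, 0 to 116 in macrophages, 0 to 36, 0 to 13, 0 to 15 in endocardial cells, 24 to 92, 3 to 78, 17 to 84 in B cells. Gene lists ranged over 15 to 16, 7 to 13, 15 to 21 in fibroblasts, 14 to 17, 11 to 18, 11 to 14 in endothelial cells, 18 to 22, 10 to 14, 9 to 17 in macrophages, 7 to 11, 8 to 16, 12 to 17 in endocardial cells, 5 to 11, 4 to 12, 11 to 15 in B cells. Shares ranged over 0 to 1 for genotype (neutrophils without db/m 1, not used because db/m 2 holds 0 neutrophils) and 0 to 0 at 14 and 20 weeks.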

Other observations

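The 3 classes in this part are not in the plan; they and the lists described for them were taken up after the data were seen, while the rule that names genes was fixed before. In pericytes, the mural cells of small vessels, the HSP70 gene Hspa1b fell at 8 weeks in db/db (266 ± 111 against 1002 ± 86.6 CPM, -1.88 ± 0.21, adjusted p = 0.000403 by edgeR). Igfbp5, which binds insulin-like growth factors, fell too (-1.78 ± 0.21, adjusted p = 0.000502), and the sodium pump subunit Atp1b1 rose (1.33 ± 0.20, adjusted p = 0.000671). The scavenger collectin Colec12 fell at 8 weeks (-1.55 ± 0.28, adjusted p = 0.00421) and rose from 8 to 14 weeks (1.68 ± 0.28, adjusted p = 0.0130). At 20 against 8 weeks the synuclein Sncg rose (479.6 ± 93.7 against 172 ± 8.42 CPM, 1.47 ± 0.16, adjusted p = 7.29e-06) and Hist1h4d fell (-1.37 ± 0.19, adjusted p = 0.000544). For genotype and 20 weeks, 46 and 25 of 8604 pericyte genes changed.

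In smooth muscle cells, elastin Eln rose from 8 to 20 weeks (432 ± 41.8 against 207 ± 49.1 CPM, 1.08 ± 0.18, adjusted p = 0.0116 by edgeR) and the actin-binding Tmsb4x rose (1.07 ± 0.20, adjusted p = 0.0468), while Bcar3 (-1.33 ± 0.18, adjusted p = 0.00219) and Hist1h4d (-1.44 ± 0.22, adjusted p = 0.00432) fell. Immediate early genes were lower at 20 weeks (adjusted p = 8.02e-30 by camera and adjusted p = 0.0230 with an estimated correlation). With them moved mitochondrially encoded genes (higher, adjusted p = 1.09e-06 by camera and adjusted p = 0.504 with an estimated correlation), ribosomal protein genes (higher, adjusted p = 0.00412 by camera and adjusted p = 0.607 with an estimated correlation) and cardiomyocyte transcripts (lower, adjusted p = 0.00473 by camera and adjusted p = 0.387 with an estimated correlation), signs of RNA quality and free RNA. For genotype the calcineurin inhibitor Rcan1 (-1.59 ± 0.26, adjusted p = 0.0427), Lmcd1 (-1.77 ± 0.23, adjusted p = 0.00528) and Dnajb1 (-1.30 ± 0.19, adjusted p = 0.0183) fell, the 3 genes that changed, named after their values were seen. At 14 and 20 weeks 6 and 30 of 9456 genes changed. In lymphatic endothelial cells Fibin rose for genotype (2.47 ± 0.28, adjusted p = 0.000190) and fell at 14 (-1.70 ± 0.25, adjusted p = 0.00815) and 20 weeks (-2.56 ± 0.28, adjusted p = 0.000485), which share the db/db 8-week libraries. The lymphatic valve factor Foxc2 rose (1.47 ± 0.20, adjusted p = 0.000258) and Swt1 fell (-1.33 ± 0.17, adjusted p = 0.000154) for genotype. Swt1 rose again at 14 against 8 weeks (1.20 ± 0.17, adjusted p = 0.00208). Its means were 188 CPM in db/m and 75.3 and 174 CPM in db/db at 8 and 14 weeks. Both of its calls thus rest on the same db/db 8-week libraries. For genotype, heat shock genes were lower (adjusted p = 1.47e-16 by camera and adjusted p = 0.0205 with an estimated correlation). Mitochondrially encoded genes (adjusted p = 8.72e-83 by camera and adjusted p = 0.0315 with an estimated correlation) and cardiomyocyte transcripts (adjusted p = 2.59e-27 by camera and adjusted p = 0.00928 with an estimated correlation), signs of RNA quality and free RNA, were lower with them. In all, 43, 8 and 14 of 9017 genes changed.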
